A study of Homo sapiens with 18 samples.

How the data were processed

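RNA was sequenced from 3 human multiple myeloma cell lines, H929, MM1S and OPM2, in 18 libraries that form 9 groups of 2. In each line, cells carrying an inducible CRISPR-Cas9 knockout of IKZF1 were set beside cells with an empty vector, all given doxycycline at 1 µg/mL for 72 h. OPM2 also had a knockout of IKZF3 and, without doxycycline, cells treated with lenalidomide at 10 µM for 72 h and untreated cells. Per the labels' protocols, live cells were sorted by flow cytometry, RNA was purified with an RNeasy Plus kit and libraries were made with a TruSeq RNA kit.

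The authors deposited a table of raw counts per Entrez gene, with 1 column per library and no normalization. Per the submitters' processing notes, the tools were Subread, featureCounts and limma and the genome build was GRCh38, with no versions or settings given. The authors also deposited a table of log2 FPKM values, described as normalized in its own name, in which each of the 4 control groups is merged into a single column. No step that made those log2 FPKM values is recorded in the labels beyond these tool names. The count table held 28395 genes, of which 385 had no symbol and took 0.0122% to 0.0276% of a library's counts. The log2 FPKM table held 16352 genes in 14 columns. Counts of mitochondrially encoded genes were absent from the table used, so the list of these genes had 0 members to test.

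Total counts ran from 11.8 to 24.19 M per library, so a floor of 3 counts was set for genes with 0 counts in a group. A fold against a group with 0 counts was given as a lower bound against that floor, taken over the group. A group with 1 to 3 counts was given a ratio with its 95% counting interval. These intervals and floors cover counting error only, since the reads carry no molecular identifiers.

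Knockout columns of the count table carry other numbers than the sample titles, so the 2 knockout libraries of a group were assigned to the group only and are called a and b here. Whether the 2 are separate clones or guides is not given in the sources used here, so n = 2 and the spread between them can include differences between clones or guides. Empty vector and untreated libraries keep their replicate numbers, and the lenalidomide titles carry the letters A and B, written here as replicate 1 and 2.

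Counts were tested with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1). Genes were filtered with filterByExpr by group, which left 14571, libraries were scaled by TMM, and 1 model with a coefficient per group was fitted to all 18 libraries with the robust quasi-likelihood method. It had 9 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 in edgeR's quasi-likelihood test, and each adjusted p for a gene in the text comes from that test unless another is named. Log2 fold changes are given ± the standard error (SE), taken from the size of the fold change and the F statistic. Levels in CPM (counts scaled to the effective size of each library) are means ± SD of 2 libraries. With 2 libraries against 2, an exact permutation test of a single gene cannot go below p = 0.333, so none was run and the tests rest on spread shared across groups and genes. The p-values measure only the spread between these samples, which may be technical, and 2 libraries of a cell line are not independent donors.

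The comparisons were IKZF1 knockout against empty vector in each line, IKZF3 knockout against empty vector, and lenalidomide against untreated cells. Also tested were the mean IKZF1 effect over the 3 lines, IKZF1 against IKZF3 knockout, the differences between the effects, and empty vector against untreated OPM2 cells. Fixed lists of genes, 26 in number, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists within a comparison. Adjusted p-values of lists in the text are camera's at the preset correlation unless stated. Members of a list were counted among the genes called over all genes, and also when adjusted over the list alone.

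Gene names in the text follow a rule. In the 5 main comparisons it gave IKZF1, IKZF3 and CD38, the 10 highest and 10 lowest fold changes among called genes with an average log2 CPM of at least 1 and with both libraries of 1 group above both of the other, and up to 4 members of each list with the smallest p. In the other comparisons it gave the 5 highest and 5 lowest. Pseudogene-like, LOC, LINC and immunoglobulin segment names were passed over. Of the genes the rule gave, those whose calls held without any 1 library were preferred, a choice made after their values were seen. The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined.

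The alternatives were other scalings (DESeq2 size factors, upper quartile), no low-count filter or a stricter one (CPM of 5 in 2 libraries), the DESeq2 1.42.0 Wald test, limma-voom, and a fit of the compared samples alone. Others were a test against a 1.5-fold change (glmTreat), an adjusted p threshold of 0.01, a log2 CPM minimum of 3 for overlaps, and each library left out in turn. Chosen after the data were seen were a correction for GC content and gene length, known for 14121 of the tested genes (96.91%), untreated OPM2 libraries as the control of the OPM2 knockouts, overlaps without OPM2 empty vector replicate 1, unrelated comparisons without either of this pair, and a replicate block for empty vector against untreated cells. Locations are on GRCh38, from the RefSeq annotation, which matched 27745 of the Entrez identifiers.

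The procedure was tested on simulated data made from the fitted levels and dispersions with a seed of 20240. Among 67 genes raised or lowered by 1.5-fold, 17.91% were recovered in the H929 comparison, 22.39% in MM1S, 20.9% in OPM2 IKZF1 knockout, 16.42% in IKZF3 knockout and 20.9% under lenalidomide. Recovery at 2-fold, in the same order, was 68.66%, 70.15%, 47.76%, 77.61% and 65.67% of 67 genes. At 4-fold it was 92.42%, 93.94%, 89.39%, 95.45% and 89.39% of 66 genes. Of 13966 unchanged genes, 10, 5, 1 and 11 were called in the 4 knockout comparisons, and 4 of 13914 were called under lenalidomide. Camera called the 1 list that had been raised (adjusted p = 7.34e-41) and 0 others. The simulated genes were drawn independently, so this does not test camera's calls where genes of a list vary together. They also held no shift of a single library across genes, such as that of OPM2 empty vector replicate 1 below. False calls from such a shift could therefore not appear. Calls per comparison numbered 106 to 137, against 1508 to 5366 in the data, so the recovery rates need not carry over. For the difference between the H929 and OPM2 effects, 152 of 395 genes changed in either line were recovered and 7 unchanged genes were called.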

Results

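Gene expression was compared by RNA sequencing in 3 multiple myeloma cell lines after loss of IKZF1 (Ikaros), and in OPM2 also after loss of IKZF3 (Aiolos) or treatment with lenalidomide, a drug that directs both proteins to degradation through cereblon. The series title names CD38, the surface protein bound by the antibody daratumumab, so the question put to each comparison was how CD38 and the genes around it in immune and plasma cell programs changed. Each of the 9 groups had 2 libraries, with 11.8 to 24.19 M counts per library. Replicates lay farther apart than counting noise alone in every group, with a ratio of chi-square to its degrees of freedom of 2.201 to 109.3. OPM2 empty vector replicate 1 stood apart from its partner: 1035 genes differed more than 2-fold between these 2 libraries, against 31 to 254 in the other groups, and its TMM factor was 0.8603. The OPM2 knockout comparisons both use it, and this pair adds to the spread shared by all comparisons, so counts without it are given beside the main ones. In comparisons that do not use this group, leaving out replicate 2 instead gave similar counts.

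IKZF1 (Entrez 10320, chromosome 7, 50303455 to 50405101) and IKZF3 (Entrez 22806, chromosome 17, 39757715 to 39864312) encode zinc finger transcription factors of lymphoid cells. Transcripts of the targeted genes were not lower in the knockout libraries, so these levels could not check the labels; a frameshift in coding sequence need not remove the mRNA. IKZF1 stood at 124 ± 5.5 CPM (SD, n = 2) in H929 empty vector and 156.2 ± 45.1 CPM after IKZF1 knockout, at 181.8 ± 4.43 and 322.5 ± 14.3 CPM in MM1S, and at 141.2 ± 66.3 and 218.7 ± 8.63 CPM in OPM2. It stood at 220.5 ± 8.07 CPM in OPM2 IKZF3 knockout, 239.2 ± 9.26 CPM under lenalidomide and 218.7 ± 9.25 CPM in untreated OPM2. The log2 fold change of IKZF1 was 0.83 ± 0.23 in MM1S (adjusted p = 0.0159 by edgeR), a call lost without any 1 of the 4 MM1S libraries (0.0533 to 0.0968). It was 0.33 ± 0.23 in H929 (adjusted p = 0.454 by edgeR). In OPM2 IKZF1 knockout it was 0.63 ± 0.23 (adjusted p = 0.0481 by edgeR, but 0.307 without empty vector replicate 1 and 0.112 and 0.152 without knockout library a and b). IKZF3 stood at 167.4 ± 21.8 and 243.2 ± 68.5 CPM in H929 without and with IKZF1 knockout and at 104.8 ± 10.1 and 168.1 ± 10.9 CPM in MM1S. In OPM2 it stood at 47.18 ± 4.48 CPM in empty vector, 67.96 ± 1.92 CPM after IKZF3 knockout and 79.8 ± 0.852 CPM after IKZF1 knockout. The change after IKZF3 knockout was 0.52 ± 0.17 (adjusted p = 0.0287 by edgeR, but 0.139 without empty vector replicate 1 and 0.122 and 0.0769 without knockout library a and b). Both of these OPM2 calls were also lost against the untreated libraries, with the compared libraries fitted alone, and with the GC and length correction, which turned the IKZF3 change to -0.0103. Under lenalidomide, neither IKZF1 (log2 fold change 0.13 ± 0.23) nor IKZF3 (0.09 ± 0.17) was called.

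CD38 (Entrez 952, chromosome 4, 15778328 to 15853232), an NAD-consuming ectoenzyme of plasma cells, was called higher in all 5 comparisons when all libraries were fitted. In H929 it went from 90.15 ± 0.157 CPM in empty vector to 336.1 ± 140 CPM after IKZF1 knockout, a log2 fold change of 1.90 ± 0.21 (adjusted p = 2.19e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In MM1S, where it was lowest, it went from 11.01 ± 0.284 to 22.19 ± 1.76 CPM, a log2 fold change of 1.01 ± 0.22 (adjusted p = 0.0036 in the same edgeR test). OPM2 empty vector held 16.51 ± 1.31 CPM, IKZF1 knockout 46.65 ± 3 CPM and IKZF3 knockout 47.98 ± 5.54 CPM, with log2 fold changes of 1.495 ± 0.21 and 1.54 ± 0.21 (adjusted p = 0.000401 and 0.000282 by edgeR). When only the compared libraries were fitted, these were 0.0498 and 0.0678, so the IKZF3 knockout call was lost, and the other 3 comparisons were called. Lenalidomide took it from 11.84 ± 1.27 to 28.45 ± 0.711 CPM, a log2 fold change of 1.27 ± 0.22 (adjusted p = 0.00173 by edgeR). The mean IKZF1 knockout effect over the 3 lines was 1.47 ± 0.12 on the log2 scale (adjusted p = 1.22e-06 by edgeR). No difference between effects was called for CD38: H929 against MM1S gave 0.89 ± 0.30 (adjusted p = 0.0595), H929 against OPM2 0.40 ± 0.29, MM1S against OPM2 -0.48 ± 0.31, and lenalidomide against IKZF1 knockout -0.23 ± 0.31, all by edgeR. In the authors' log2 FPKM table, the H929 knockout columns read 8.17 and 7.32 against 5.91 in the merged control, those of MM1S 3.92 and 3.76 against 2.81, and lenalidomide 4.22 and 4.28 against 3.01. The OPM2 merged empty vector column read 3.54, against 4.90 and 5.03 after IKZF1 knockout and 4.88 and 5.11 after IKZF3 knockout.

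**Figure D1:**
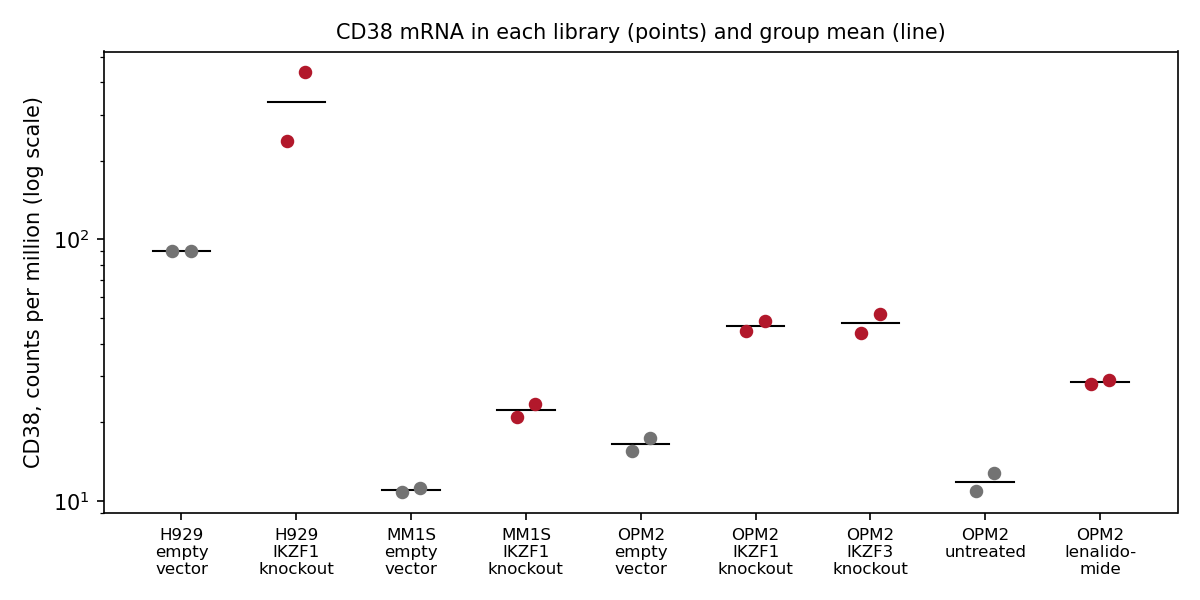
CD38 level in CPM on a log axis for each library, by group. Points are single libraries and lines are group means, and both libraries of each knockout or lenalidomide group lie above both of their controls.

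In H929, loss of IKZF1 was followed by a rise of 55 of 57 interferon-stimulated genes, and of 11 of 22 genes of MHC class I, 10 of 16 of MHC class II and 10 of 23 linked to interferon gamma and NF-kB. In the lists of cholesterol synthesis and of the B cell program 9 of 29 and 6 of 19 genes fell, with 1 and 2 higher. Of the 11 lists called in H929, 2 were called with an estimated correlation, those of type I interferon and of MHC class II. The D-type cyclins went opposite ways, CCND2 down and CCND3 up. Of 14571 genes, 862 rose and 670 fell, 1532 in all by edgeR's quasi-likelihood test, of which 485 and 336 changed more than 2-fold. The count was 696 without empty vector replicate 1, 690 without replicate 2, 829 without knockout library a, and 3266 and 3323 without OPM2 empty vector replicate 1 and 2.

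All but 2 of the 57 type I interferon-stimulated genes rose in H929 (55 over all genes, 56 adjusted over the list alone), with a median log2 fold change of 3.73 and a camera adjusted p of 4.18e-139, or 0.00545 with an estimated correlation. The inducible mitochondrial protein gene IFI27 rose by 8.40 ± 0.41 on the log2 scale (adjusted p = 9.95e-09 by edgeR), from 1.905 to 648.5 CPM. The viral entry inhibitor IFITM1 rose by 7.05 ± 0.35, from 4.903 to 651.9 CPM, and its neighbour IFITM2 was 1820-fold higher (95% counting interval 326 to 71900). LGALS3BP, a secreted galectin ligand, rose by 8.19 ± 0.54, the apoptosis factor XAF1 by 7.73 ± 0.54 and IFI44L by 7.77 ± 0.72. USP18, which removes ISG15 from proteins and restrains the receptor, rose by 6.69 ± 0.49, PARP14 by 6.13 ± 0.34 and DTX3L by 5.93 ± 0.30. The death ligand TNFSF10 (TRAIL) rose by 6.82 ± 0.59. The collagenase MMP13 rose from 0.842 CPM (adjusted p = 1.59e-05 by edgeR), with an SD of 468 around its mean of 429.1 CPM between the knockout libraries.

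Among genes of MHC class I presentation, 11 of 22 rose in H929 (15 adjusted over the list alone, with 1 lower; camera adjusted p = 7.08e-09, or 0.23 with an estimated correlation). The peptide transporter TAP1 rose from 138.4 to 745.3 CPM (log2 fold change 2.43 ± 0.23), HLA-F by 2.09 ± 0.24, the immunoproteasome subunit PSMB8 by 1.17 ± 0.21 and the light chain B2M by 0.95 ± 0.15. Of 16 MHC class II genes, 10 rose (13 adjusted over the list alone, with 1 lower; adjusted p = 4.18e-10, or 0.0396 with an estimated correlation), led by HLA-DPA1 at 3.98 ± 0.37 and HLA-DRB1 at 2.51 ± 0.38, with the class II transactivator CIITA at 1.92 ± 0.29. Among genes linked to interferon gamma and NF-kB, 10 of 23 rose (13 adjusted over the list alone; adjusted p = 4.03e-08, or 0.23 with an estimated correlation), among them the chemokine CCL4 (4.04 ± 0.35), CASP1 (2.18 ± 0.36) and IRF1 (1.65 ± 0.21). Single libraries moved these counts: the class I count was 4, 6 and 5 and the interferon gamma count 6, 5 and 5 without empty vector replicate 1, replicate 2 and knockout library a, and the class II count was 6 without empty vector replicate 1.

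In H929 the G1 cyclin CCND2 fell by 6.61 ± 0.17 on the log2 scale (adjusted p = 3.74e-12 by edgeR), from 273.9 to 2.796 CPM, while CCND3 rose by 1.04 ± 0.16. The B cell list had 2 genes higher and 6 lower of 19 (3 and 6 adjusted over the list alone; camera adjusted p = 0.00272, or 0.23 with an estimated correlation, and 0.127 without knockout library b). FCRLA, an Fc receptor-like protein of the endoplasmic reticulum, changed by -4.07 ± 0.40, the kinase BTK was 120-fold lower (95% counting interval 21.3 to 4770), and the Ets factor SPI1 was at least 34.1-fold lower against the 3-count floor over the group. The interleukin-4 receptor IL4R rose by 1.198 ± 0.16. The leucocyte phosphatase partner PTPRCAP was 2280-fold lower (95% counting interval 410 to 90200) and the clock repressor BHLHE41 576-fold lower (103 to 22800). The surface target list gave 3 higher and 4 lower of 21 and was not called (camera adjusted p = 0.81). Of its members and other surface proteins, syndecan-1 (SDC1) changed by -0.77 ± 0.12, from 703.7 to 413.2 CPM, the plasma cell receptor FCRL5 by -1.55 ± 0.29, and CD55, which shields cells from complement, by -1.55 ± 0.14, from 38.57 to 13.18 CPM.

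Of 29 genes of cholesterol and fatty acid synthesis, 9 fell and 1 rose in H929 (the same numbers adjusted over the list alone; adjusted p = 0.000119, or 0.269 with an estimated correlation), among them FADS1 (-1.06 ± 0.15) and DHCR7 (-0.81 ± 0.15). That lower count was 4 without empty vector replicate 1, 3 without replicate 2, 4 without knockout library a and 14 without OPM2 empty vector replicate 1. In the BCL2 family and cell death list 8 of 28 rose (10 adjusted over the list alone; adjusted p = 3.42e-05, or 0.132 with an estimated correlation), with the survival factor MCL1 at 1.01 ± 0.13. The count was 2 without empty vector replicate 1 and 3 without replicate 2 or knockout library a. MYC targets were called lower as a list (4 of 45 genes, also 4 adjusted over the list alone; adjusted p = 0.00316, 0.476 with an estimated correlation and 0.241 without knockout library b). The polyamine enzyme ODC1 changed by -1.08 ± 0.10 and the pyrimidine enzyme CAD by -0.76 ± 0.13. Cell cycle genes were called lower as a list with 2 of 45 members lower (adjusted p = 0.00745, 0.602 with an estimated correlation and 0.649 without knockout library a). So were ribosomal protein genes, with 1 of 78 lower (adjusted p = 0.01, 0.814 with an estimated correlation and 0.102 without empty vector replicate 2). Genes of T and NK cells were lower (3 of 8, 6 adjusted over the list alone; adjusted p = 0.00525, or 0.23 with an estimated correlation), with perforin (PRF1) at -3.70 ± 0.63. Of 25 lists tested, 14 were not called, with a lowest adjusted p of 0.0829 for the stress response list.

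**Figure D2:**
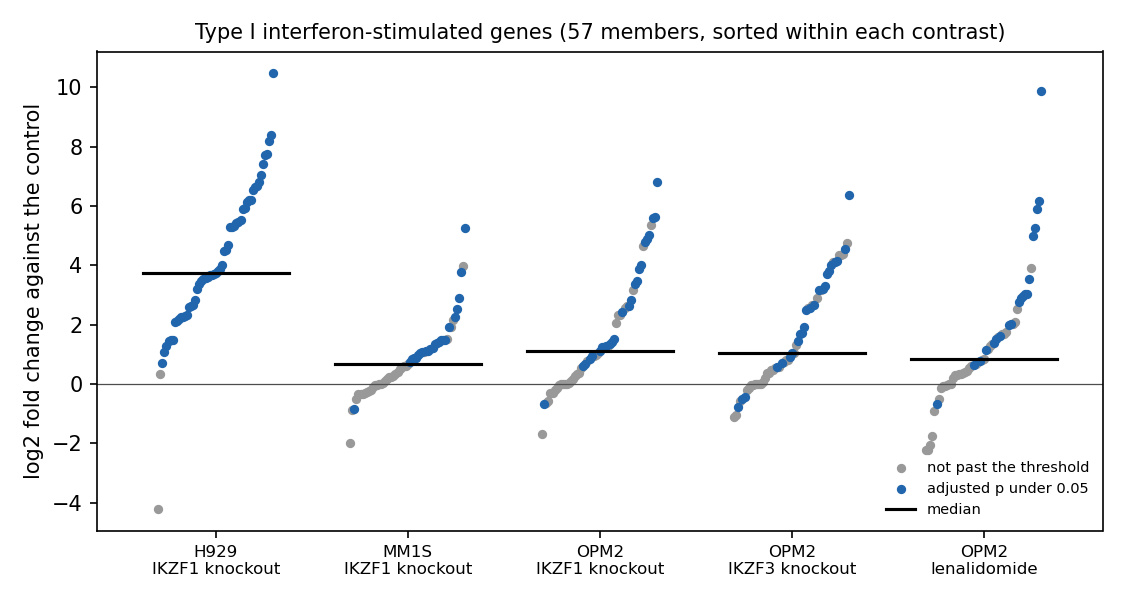
Log2 fold change of each type I interferon-stimulated gene in the 5 comparisons, 57 genes per column. Points are genes (blue where called by edgeR, grey where not) and bars are medians, 3.73 in H929, 0.69 in MM1S, 1.12 and 1.06 in the OPM2 knockouts of IKZF1 and IKZF3, and 0.85 under lenalidomide.

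In MM1S, 11 of 22 plasma cell genes rose after loss of IKZF1, while 19 of 45 genes of cell division and 16 of 45 MYC targets fell. Of the 33 genes of the unfolded protein and amino acid stress response, 19 fell and 9 rose. Of the 11 lists that camera called in MM1S, 0 were called with an estimated correlation, and fry called 17 lists. By edgeR's quasi-likelihood test 2273 genes rose and 1841 fell, 4114 in all, of which 1150 and 702 changed more than 2-fold. The count was 2360 without empty vector replicate 1, 2479 without replicate 2, 2490 without knockout library b, and 6312 and 6324 without OPM2 empty vector replicate 1 and 2.

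Among the largest rises in MM1S, the chemokine receptor CX3CR1 changed by 6.39 ± 0.42 on the log2 scale (adjusted p = 1.16e-07 by edgeR), from 1.794 to 151.3 CPM. The Wnt ligand WNT5A rose by 5.84 ± 0.34 and MME (neprilysin, also known as CALLA) by 5.37 ± 0.33, from 6.734 to 278.5 CPM. QPRT, an enzyme of NAD synthesis, was 776-fold higher (95% counting interval 214 to 6410) and the calcium channel RYR1 at least 28-fold higher against the 3-count floor over the group. At the other end, the integrin activator FERMT3 fell by 5.91 ± 0.26 (adjusted p = 6.83e-09 by edgeR), from 126.5 to 2.04 CPM. The motor protein MYO1F changed by -5.93 ± 0.35, the inositol phosphatase SYNJ2 by -7.03 ± 0.49 and the RNA editor ADARB1 by -5.94 ± 0.50, and GPAT2 was at least 167-fold lower against the same floor.

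Plasma cell genes rose in MM1S, 11 of 22 with 0 lower by edgeR (the same adjusted over the list alone; camera adjusted p = 0.000477, or 0.0595 with an estimated correlation). They included the secretory regulator XBP1 (0.80 ± 0.09), the antibody joining chain JCHAIN (0.74 ± 0.10), the receptor subunit CD79B (3.10 ± 0.32) and SDC1 (1.18 ± 0.12), which went from 735.6 to 1671 CPM. Myeloma surface targets gave 8 higher and 1 lower of 21 (the same adjusted over the list alone; adjusted p = 0.011, or 0.0908 with an estimated correlation), and 5 higher without any 1 MM1S library. The adhesion molecule NCAM1 rose by 2.56 ± 0.29 and the SLAM receptor LY9 by 1.33 ± 0.16. Of the complement inhibitors, CD59 rose by 1.36 ± 0.12 while CD55 changed by -1.42 ± 0.14, from 19.35 to 7.23 CPM. The B cell list was not called by camera (adjusted p = 0.163): of 19 genes 3 were lower, SPIB (-2.96 ± 0.43), BTK (-2.61 ± 0.24) and FCRLA (-2.93 ± 0.29), and 1 was higher, BLNK (1.27 ± 0.26). Myeloid marker genes were higher (5 of 8, also 5 adjusted over the list alone; adjusted p = 0.0144, 0.111 with an estimated correlation, and 0.0704 and 0.0663 without OPM2 empty vector replicate 1 and 2), with the lipopolysaccharide co-receptor CD14 at 3.44 ± 0.55. That count was 1, 2 and 3 without empty vector replicate 1, replicate 2 and knockout library a.

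Of 33 genes of the unfolded protein and amino acid stress response, 19 fell and 9 rose in MM1S (19 and 10 adjusted over the list alone; adjusted p = 5.01e-07, or 0.0908 with an estimated correlation). The serine synthesis enzyme PSAT1 fell by 2.84 ± 0.21, from 244.5 to 34.05 CPM, with asparagine synthetase ASNS at -1.86 ± 0.17, the pseudokinase TRIB3 at -1.97 ± 0.16 and the factor CEBPB at -2.10 ± 0.18. Among cell cycle genes 19 of 45 fell (20 adjusted over the list alone; adjusted p = 6.8e-07, or 0.385 with an estimated correlation), including the replication clamp PCNA, which fell by 1.73 ± 0.13 from 325.9 to 97.93 CPM, E2F2 (-1.198 ± 0.15) and CCNE1 (-0.97 ± 0.15). MYC targets gave 16 lower and 1 higher of 45 (17 and 2 adjusted over the list alone; adjusted p = 0.000477, or 0.385 with an estimated correlation), with the nucleolar protein NOP56 at -1.05 ± 0.18 and lactate dehydrogenase LDHA at -0.89 ± 0.11. Without empty vector replicate 1, replicate 2 and knockout library b the cell cycle count was 8, 9 and 6 and the MYC target count 7, 8 and 5, and without OPM2 empty vector replicate 1 they were 30 and 26. The migration gene vimentin (VIM) fell by 2.85 ± 0.21, from 484.6 to 67.3 CPM, and the endothelial adhesion molecule PECAM1 rose by 3.21 ± 0.19.

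The type I interferon list in MM1S had 23 genes higher and 1 lower of 57 (24 and 2 adjusted over the list alone; median 0.69; adjusted p = 0.000477, or 0.612 with an estimated correlation). The count was 14, 13 and 13 without empty vector replicate 1, replicate 2 and knockout library a. LGALS3BP rose by 5.25 ± 0.56, the antiviral GTPase MX2 by 3.78 ± 0.48 and the nuclear body protein SP100 by 1.39 ± 0.16. MHC class I genes gave 13 of 22 higher (also 13 adjusted over the list alone; adjusted p = 0.000664, or 0.472 with an estimated correlation), and 8 without empty vector replicate 2 or knockout library b. The transactivator NLRC5 rose by 1.21 ± 0.16. MHC class II genes gave 7 higher and 1 lower of 16 (9 and 2 adjusted over the list alone; adjusted p = 0.00347, or 0.295 with an estimated correlation), 3 higher without empty vector replicate 2 and 11 without OPM2 empty vector replicate 1. The adhesion ligand ICAM1 rose by 2.53 ± 0.20 and CD40 by 1.29 ± 0.24. Targets of p53 were called as a list (9 higher and 2 lower of 29, the same adjusted over the list alone; adjusted p = 0.0484, or 0.283 with an estimated correlation), a call lost without empty vector replicate 1 (0.0588), replicate 2 (0.0694) or knockout library a (0.17). Immediate early and heat shock genes gave 7 lower and 2 higher of 25 (9 and 2 adjusted over the list alone; adjusted p = 0.0258, or 0.34 with an estimated correlation). The lower count was 3 without empty vector replicate 1 or knockout library b and 11 without OPM2 empty vector replicate 1. The 14 lists not called had a lowest adjusted p of 0.0806.

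In OPM2, loss of IKZF1 raised CD38, the transcription factors MAF and KLF4 and 23 of 57 interferon-stimulated genes. Of 33 genes of the unfolded protein and amino acid stress response, 18 fell. Ribosomal protein and respiratory chain genes were also lower than in the empty vector, but these moved with OPM2 empty vector replicate 1 and with the choice of control. Of the 7 lists that camera called, 0 were called with an estimated correlation, and fry called 9 lists. By edgeR's quasi-likelihood test 2365 genes rose and 2918 fell, 5283 in all, of which 883 and 544 changed more than 2-fold. The count was 3163 without empty vector replicate 1, 7982 without replicate 2, 3112 without knockout library a, 3384 without knockout library b, 114 when only these 4 libraries were fitted, and 1131 against the untreated OPM2 libraries.

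The calcium-binding protein S100A16 rose by 7.53 ± 0.50 on the log2 scale (adjusted p = 3.41e-06 by edgeR), from 0.2661 to 43.54 CPM, and the leukotriene receptor CYSLTR1 by 6.21 ± 0.63. LGALS3BP was 54.9-fold higher (95% counting interval 14.8 to 459), the Hippo pathway protein AJUBA at least 15.9-fold higher and carbonic anhydrase-like CA8 at least 5.18-fold lower, both bounds against the 3-count floor over the group. Interferon-stimulated genes gave 23 higher and 1 lower of 57 (23 and 2 adjusted over the list alone; median 1.12; adjusted p = 1.4e-09, or 0.603 with an estimated correlation). Without empty vector replicate 1, 16 were higher with a median of 1.02, and against the untreated libraries 12 were higher with a median of 0.36. Among them the antiviral RNA-binding IFIT3 rose by 4.77 ± 0.39, from 1.034 to 29.17 CPM, IFIT5 by 4.89 ± 0.44, PARP14 by 3.46 ± 0.45 and the RNA sensor OAS2 by 2.64 ± 0.32. ICAM1 was 20.9-fold higher (95% counting interval 3.32 to 867).

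Among surface proteins in OPM2 without IKZF1, the hyaluronan receptor CD44 changed by -1.19 ± 0.22, the SLAM ligand CD48 by -0.94 ± 0.14 and BCMA (TNFRSF17) by -0.67 ± 0.14, while the nectin NECTIN2 rose by 1.80 ± 0.32. The surface target list as a whole was not called (adjusted p = 0.676). These 4 genes were not called when only the compared libraries were fitted, and the same holds for the other genes of this paragraph except MAF, KLF4, CMBL and CD68. The adaptor BLNK rose by 1.98 ± 0.30 and the hydrolase gene CMBL by 2.82 ± 0.29. The myeloma oncogene MAF rose by 1.74 ± 0.16 (adjusted p = 9.06e-06 by edgeR), from 64.51 to 216.4 CPM, KLF4 by 2.29 ± 0.34, and the lysosomal glycoprotein CD68 by 3.46 ± 0.37, from 2.098 to 22.23 CPM. The cell cycle inhibitor CDKN1A rose by 1.24 ± 0.14 and GADD45A by 1.43 ± 0.22. Stress response genes gave 18 lower and 3 higher of 33 (18 and 4 adjusted over the list alone; median -0.43; camera adjusted p = 0.000889, or 0.512 with an estimated correlation), 14 lower without empty vector replicate 1 and 16 against the untreated libraries. TRIB3 changed by -1.52 ± 0.16, the leucine sensor SESN2 by -0.91 ± 0.12, and the paired amino acid transporter chains SLC7A5 and SLC3A2 by -1.18 ± 0.15 and -1.14 ± 0.16.

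Ribosomal protein genes were lower in 76 of 78 cases after IKZF1 knockout (77 adjusted over the list alone; median -0.93; adjusted p = 1.42e-27, or 0.576 with an estimated correlation). The median was -0.48, with 68 lower, without empty vector replicate 1, and -0.12, with 0 called by edgeR, against the untreated libraries, where 1131 genes were called over all genes. Respiratory chain genes gave 38 lower and 1 higher of 41 (40 and 1 adjusted over the list alone; median -0.79; adjusted p = 1.52e-14, or 0.576 with an estimated correlation), a median of -0.39 without that library and -0.04 against the untreated ones. MYC targets gave 32 lower and 2 higher of 45 (35 and 3 adjusted over the list alone; median -0.60; adjusted p = 8.86e-10, or 0.444 with an estimated correlation), a median of -0.44 without that library and 0.17 against the untreated ones. Glycolysis and hypoxia genes gave 14 lower and 2 higher of 30 (15 and 3 adjusted over the list alone; median -0.52; adjusted p = 0.0128, or 0.801 with an estimated correlation), with 10 lower without that library and 11 against the untreated ones. Translocation and line identity genes, which hold MAF, gave 5 higher of 11 (5 and 1 lower adjusted over the list alone; adjusted p = 0.0171, 0.399 with an estimated correlation, 0.0949 without empty vector replicate 2, and 0.583 against the untreated libraries). The 18 lists not called had a lowest adjusted p of 0.0948.

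In OPM2, loss of IKZF3 gave a response close in outline to that of IKZF1, with CD38, CD68 and 21 of 57 interferon-stimulated genes higher. Genes of the unfolded protein and amino acid stress response fell further, and MYC itself was lower. Of the 7 lists called, 1, the stress response list, was called with an estimated correlation. By edgeR's quasi-likelihood test 2360 genes rose and 3006 fell, 5366 in all, of which 819 and 676 changed more than 2-fold. The count was 3505 without empty vector replicate 1, 2539 without knockout library a, 52 when only these 4 libraries were fitted, and 1205 against the untreated OPM2 libraries.

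CX3CR1 rose by 5.38 ± 0.44 on the log2 scale (adjusted p = 5e-06 by edgeR), from 0.9379 to 40.65 CPM, the membrane protein MLC1 by 4.82 ± 0.73, and CD68 by 3.78 ± 0.36, from 2.098 to 27.86 CPM. MYO1F and CACNA1A were at least 9.67-fold and 11.6-fold higher, and the adaptor of Toll-like receptors TIRAP at least 8.88-fold lower, against the 3-count floor over the group. The interferon list gave 21 higher and 3 lower of 57 (24 and 3 adjusted over the list alone; median 1.06; camera adjusted p = 5.79e-09, 0.66 with an estimated correlation, and 0.051 without empty vector replicate 2). Without empty vector replicate 1, 13 were higher, and against the untreated libraries 9 were, with a median of 0.53. IFIT3 rose by 4.14 ± 0.40, from 1.034 to 18.65 CPM, PARP9 by 3.71 ± 0.40 and OAS2 by 2.49 ± 0.32. Stress response genes gave 20 lower and 1 higher of 33 (the same adjusted over the list alone; median -1.01; adjusted p = 4.13e-14, or 0.0374 with an estimated correlation), 19 lower without empty vector replicate 1 and 20 against the untreated libraries. SESN2 fell by 2.24 ± 0.13, from 172.2 to 36.41 CPM, TRIB3 changed by -2.25 ± 0.16, ASNS by -1.79 ± 0.16, the serine enzyme PSPH by -1.61 ± 0.13 and the stress factor ATF3 by -1.08 ± 0.14. MYC fell by 1.32 ± 0.15, from 562 to 224.7 CPM, and the receptor FGFR3 changed by -1.42 ± 0.30. MCL1 rose by 0.85 ± 0.13, IL4R by 0.80 ± 0.14 and KLF4 by 1.73 ± 0.34, while CD48 changed by -0.76 ± 0.14 and the complement receptor CR2 by -2.33 ± 0.49. Calls of MYC, PSPH, ATF3, FGFR3, MCL1, IL4R, KLF4, CD48, CR2, OAS2, CACNA1A and MYO1F were lost when only the compared libraries were fitted.

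Ribosomal protein, respiratory chain and MYC target genes were lower after IKZF3 knockout as well, 76 of 78, 37 of 41 and 32 of 45 by edgeR (76, 37 and 35 adjusted over the list alone). Their medians were -0.89, -0.77 and -0.66, with camera adjusted p-values of 2.92e-23, 9.17e-12 and 8.24e-10, or 0.66, 0.66 and 0.292 with an estimated correlation. Without empty vector replicate 1 the medians were -0.44, -0.35 and -0.44, and against the untreated libraries they were -0.05, 0.03 and 0.21. Glycolysis and hypoxia genes gave 12 lower and 2 higher of 30 (the same adjusted over the list alone; adjusted p = 0.0287, 0.676 with an estimated correlation, and 0.075 without knockout library b). Line identity genes gave 6 higher and 1 lower of 11 (7 and 1 adjusted over the list alone; adjusted p = 0.0245, 0.224 with an estimated correlation, 0.0778 without empty vector replicate 2, and 0.591 against the untreated libraries). The 18 lists not called had a lowest adjusted p of 0.154.

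**Figure D3:**
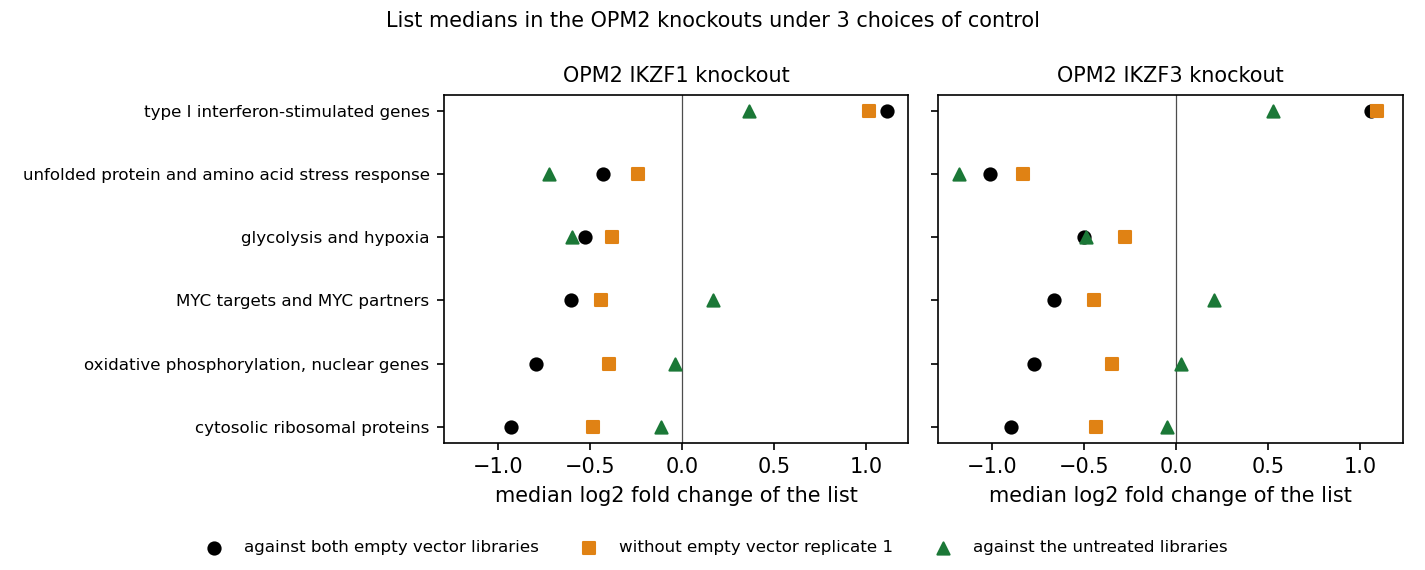
Median log2 fold change of 6 gene lists in the OPM2 knockouts, against both empty vector libraries, without empty vector replicate 1, and against the untreated libraries. The ribosomal protein median after IKZF1 knockout was -0.93, -0.48 and -0.12 in turn.

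The OPM2 empty vector and untreated libraries, which differ by the vector and doxycycline, were compared to set the control values side by side. In this comparison 2837 genes were higher and 2303 lower in the empty vector by edgeR, 5140 in all (3122 without empty vector replicate 1, 7842 without replicate 2, 2767 without untreated replicate 1 and 2187 without untreated replicate 2). Fitted on their own, these 4 libraries gave 0 calls by edgeR, with 2748 genes at an unadjusted p below 0.05, while DESeq2 and limma-voom on all libraries gave 5573 and 5280. The excess of higher genes was not kept in edgeR with DESeq2 size factors (2591 higher and 2670 lower) or upper-quartile scaling (2588 and 2666). Ribosomal protein genes were higher in the empty vector, 75 of 78 with a median of 0.81 (camera adjusted p = 1.66e-22, or 0.649 with an estimated correlation), and so were 35 of 41 respiratory chain genes, with a median of 0.78 (adjusted p = 1.17e-14, or 0.649). The interferon list was lower, with 11 genes lower and 2 higher (median -0.53; adjusted p = 0.0166, 0.807 with an estimated correlation and 0.614 without empty vector replicate 2). The hypoxia enzyme P4HA1 changed by -2.18, and carbonic anhydrase CA9 was at least 20.5-fold lower in the empty vector against the 3-count floor over the group. CD38 was not called (0.49 ± 0.22).

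Loss of IKZF1 and of IKZF3 was compared directly to ask where the 2 factors part. By edgeR 249 genes were higher and 129 lower after IKZF1 knockout than after IKZF3 knockout, 378 in all (478 and 398 with the GC and length correction). The count was 114 and 208 without IKZF3 knockout library a and b, 246 and 225 without IKZF1 knockout library a and b, and 1328 and 1334 without OPM2 empty vector replicate 1 and 2. The stress response list was higher after IKZF1 knockout, 8 of 33 genes (16 and 1 lower adjusted over the list alone; adjusted p = 2.92e-14, or 0.0347 with an estimated correlation). That number was 2, 3, 3 and 5 without IKZF3 knockout library a and b and IKZF1 knockout library a and b, and 17 without either empty vector library. Myeloma surface targets were lower after IKZF1 than after IKZF3 knockout (3 of 21, also 3 adjusted over the list alone; adjusted p = 0.0025, 0.0413 with an estimated correlation and 0.0702 without IKZF1 knockout library b). So were adhesion and migration genes (3 of 35, with 1 higher; adjusted p = 0.0025, 0.176 with an estimated correlation and 0.056 without IKZF1 knockout library a). MHC class I and cell cycle genes were also called lower as lists (adjusted p = 0.00657 and 0.0478, each 0.949 with an estimated correlation), with 0 of 22 and 1 of 45 members called by edgeR among 1944 genes at an unadjusted p below 0.05. The class I call was lost without IKZF1 knockout library a (0.056) or IKZF3 knockout library b (0.0925), and the cell cycle call without these (0.471 and 0.161) or IKZF3 knockout library a (0.0536). The phosphatase-like secretory granule protein PTPRN2 was higher by 4.20 ± 0.45 (adjusted p = 0.000271 by edgeR), and MEGF6 and C16orf54 differed by -2.94 ± 0.37 and -4.20 ± 0.49. CD38 did not differ (-0.04 ± 0.20).

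The genes changed by both knockouts overlapped, 1636 higher in both (383 by chance, the product of the counts over the genes tested) and 2274 lower in both (602 by chance), with 17 and 2 in opposite directions. That product takes the 2 comparisons as independent, which they are not, since they share their control libraries. The numbers by chance in this paragraph are therefore no null for these overlaps. Across genes, which are not independent replicates, Pearson's r of the fold changes was 0.71 and Spearman's rho 0.785. Both use the same empty vector libraries, and simulated knockouts with no change gave r of 0.50 (0.4699 to 0.5364 over 20 simulations), a covariance of 0.126 against 0.673 in the data, and 0 genes called in both by edgeR. The spread between the 2 empty vector libraries gives an estimate of 0.1098 for the part of that covariance that comes from the shared controls. The simulations drew each gene on its own around the mean of the empty vector group. They held no shift of replicate 1 across genes and no offset of that group from untreated cells. Their 0 shared calls are therefore no null for the shared counts. Against the untreated libraries, where 1131 and 1205 genes were called by edgeR, no overlap was counted. Without empty vector replicate 1 the shared counts were 1103 higher (210.6 by chance) and 997 lower (170.9).

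Lenalidomide was compared with untreated OPM2 cells to set the drug beside loss of its targets. It raised CD38, S100A16 and 19 of 57 interferon-stimulated genes, and lowered MYC and 16 of 30 glycolysis and hypoxia genes. It also lowered 18 of 33 genes of the unfolded protein and amino acid stress response. Of the 11 lists called, 1, the stress response list, was called with an estimated correlation. Of 21 myeloma surface targets 5 fell, among them SLAMF7, and 2 rose. By edgeR's quasi-likelihood test 840 genes rose and 668 fell, 1508 in all, of which 432 and 239 changed more than 2-fold. The count was 634 and 639 without lenalidomide replicate 1 and 2, 583 and 645 without untreated replicate 1 and 2, and 3265 and 3266 without OPM2 empty vector replicate 1 and 2.

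S100A16 rose by 6.70 ± 0.49 on the log2 scale under lenalidomide (adjusted p = 2.6e-06 by edgeR), from 0.281 to 29.96 CPM, IFI27 by 5.90 ± 0.47 and CYSLTR1 by 5.87 ± 0.51, and LGALS3BP was 1190-fold higher (95% counting interval 213 to 47000). The interferon list gave 19 higher and 1 lower of 57 (22 and 3 adjusted over the list alone; median 0.85; camera adjusted p = 1.33e-13, or 0.354 with an estimated correlation), 12 without lenalidomide replicate 1 and 11 without replicate 2 or either untreated library. IFIT3 rose by 5.25 ± 0.37, from 1.533 to 58.94 CPM, and IFIT5 by 2.98 ± 0.32. MUC1, an epithelial mucin also found on plasma cells, was 49.1-fold higher (95% counting interval 8.3 to 1990). KLF4 rose by 3.11 ± 0.34, the Wnt inhibitor DKK1 by 2.29 ± 0.30, CD68 by 3.27 ± 0.34, the chemokine receptor CXCR3 by 1.86 ± 0.27, BLNK by 1.90 ± 0.29 and MAF by 0.90 ± 0.15. MHC class I genes were called higher as a list (4 of 22, 7 adjusted over the list alone; adjusted p = 0.0221, 0.652 with an estimated correlation and 0.0571 without untreated replicate 2). Without any 1 of the 4 libraries 0 members were called by edgeR, in fits with 2254 to 2331 genes at an unadjusted p below 0.05, and 9 were called without OPM2 empty vector replicate 1. MHC class II genes were lower (2 of 16, 4 adjusted over the list alone; adjusted p = 0.01, 0.356 with an estimated correlation, 0.0587 without untreated replicate 1, and 0.0572 and 0.0564 without OPM2 empty vector replicate 1 and 2).

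Among genes lowered by lenalidomide, the stress response list gave 18 of 33 by edgeR (19 with 1 higher adjusted over the list alone; median -1.23; camera adjusted p = 3.86e-39, or 0.000817 with an estimated correlation). SESN2 fell by 3.04 ± 0.13 (adjusted p = 1.05e-08), from 294.3 to 35.73 CPM, the glutathione-degrading enzyme CHAC1 changed by -3.47 ± 0.26, ASNS by -2.48 ± 0.17, and CEBPB and TRIB3 each by -2.20 ± 0.16. The activin subunit INHBE changed by -3.62 ± 0.23 and the adhesion protein FLRT1 by -4.88 ± 0.27, from 30.98 to 1.042 CPM. Surface targets gave 5 lower and 2 higher of 21 (7 and 2 adjusted over the list alone; adjusted p = 0.00782, or 0.0755 with an estimated correlation), 3 lower without lenalidomide replicate 1 or 2 and 8 without OPM2 empty vector replicate 1. SLAMF7, the target of elotuzumab, fell by 1.99 ± 0.22, from 587.3 to 147.5 CPM, with CD44 at -1.09 ± 0.21 and CD48 at -1.01 ± 0.14. CD55 changed by -0.90 ± 0.13, from 39.51 to 21.19 CPM, and the NK cell ligand MICB by -0.85 ± 0.13, while NECTIN2 rose by 1.79 ± 0.32. MYC fell by 1.29 ± 0.15, from 535.9 to 219 CPM. Glycolysis and hypoxia genes gave 16 of 30 lower (21 adjusted over the list alone; adjusted p = 2.07e-13, or 0.0755 with an estimated correlation), and 9, 7 and 8 without lenalidomide replicate 1, replicate 2 and untreated replicate 1. VEGFA changed by -1.07 ± 0.14 and the kinase PGK1 by -0.65 ± 0.11.

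Other lists were also called lower under lenalidomide. MYC targets gave 8 of 45 lower (9 adjusted over the list alone; adjusted p = 0.00132, or 0.51 with an estimated correlation), 3 without any 1 of the 4 libraries and 14 without OPM2 empty vector replicate 1. Ribosomal protein genes gave 10 of 78 lower (12 adjusted over the list alone; median -0.41; adjusted p = 4.12e-11, or 0.553 with an estimated correlation). The count was 1 and 2 without lenalidomide replicate 2 and untreated replicate 2, 58 without OPM2 empty vector replicate 1, and 0 by edgeR without lenalidomide or untreated replicate 1, in fits with 2256 and 2254 genes at an unadjusted p below 0.05. Cell cycle genes gave 3 of 45 lower (adjusted p = 0.000476, or 0.553 with an estimated correlation). Targets of p53 gave 4 higher and 4 lower of 29 (adjusted p = 0.0268, 0.227 with an estimated correlation and 0.0726 without lenalidomide replicate 1). Respiratory chain genes, the last of 11 lists called, gave 1 of 41 lower (adjusted p = 0.00688, 0.733 with an estimated correlation and 0.0587 without untreated replicate 1). The 14 others had a lowest adjusted p of 0.0545.

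Lenalidomide and the IKZF1 knockout, which share no libraries, changed 535 genes upward in common (136.3 by chance) and 340 downward (133.8 by chance), with 5 and 8 in opposite directions. For IKZF3 knockout the shared genes numbered 421 (136.1 by chance) and 337 (137.8 by chance), with 32 and 35 in opposite directions. Without OPM2 empty vector replicate 1 these counts were 851 and 635 for IKZF1 knockout and 731 and 643 for IKZF3 knockout. Across genes, Pearson's r of the fold changes was 0.43 with IKZF1 knockout and 0.31 with IKZF3 knockout. CD38, S100A16, CYSLTR1, IFIT3, KLF4 and CD68 rose and SESN2, TRIB3, CD44 and CD48 fell both under lenalidomide and after IKZF1 knockout.

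A test of the difference between the lenalidomide and IKZF1 knockout effects called 10 genes higher and 31 lower under lenalidomide by edgeR, 41 in all. It called 268 and 272 with the GC and length correction, 1746 in all by DESeq2 and 2297 in all without a low-count filter. At an unadjusted p below 0.05 by edgeR stood 4070 genes, so a count of 41 does not show that the 2 effects were alike. The count was 542 and 6604 without OPM2 empty vector replicate 1 and 2, 13 and 11 without lenalidomide replicate 1 and 2, 10 and 15 without untreated replicate 1 and 2, and 26 without MM1S empty vector replicate 1. FLRT1 differed by -3.35 ± 0.34 (adjusted p = 0.000378 by edgeR) and INHBE by -2.68 ± 0.30, and the arginase ARG2 by 1.73 ± 0.23. Against the IKZF3 knockout effect the protease TMPRSS2 differed by 4.16 ± 0.60 and the receptor P2RY10 by -4.71 ± 0.70. In all, 962 genes differed, 511 higher and 451 lower (397 and 522 with DESeq2 size factors, 448 and 474 with upper-quartile scaling). That count was 104 and 482 without IKZF3 knockout library a and b, 6739 without OPM2 empty vector replicate 2 and 1203 without replicate 1, 108 and 77 without lenalidomide replicate 1 and 2, and 95 and 100 without untreated replicate 1 and 2. Libraries of the other lines moved it too, to 406 to 493 without single empty vector libraries of H929 or single libraries of MM1S.

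Across the 3 lines, the question was which genes answer to loss of IKZF1 in each. By edgeR 157 genes rose in 3 of 3 lines (21.83 by chance) and 49 fell (16.95 by chance), and without OPM2 empty vector replicate 1 the counts were 306 (43.84 by chance) and 174 (33.36 by chance). CD38 was among those that rose, with the RNA helicase-like DDX60L (5.27, 3.20 and 3.75 in H929, MM1S and OPM2) and LGALS3BP, given above. Among those that fell were CD55 (-1.55, -1.42 and -0.52), a call lost in OPM2 without knockout library b (adjusted p = 0.0531 by edgeR), and the actin regulator COTL1 (-1.74, -3.24 and -0.98), named here after its values were seen. Across genes, Pearson's r between lines was 0.0874 for H929 and MM1S, 0.127 for H929 and OPM2 and 0.163 for MM1S and OPM2. Genes higher in both lines exceeded chance in each pair. Genes lower in both numbered 129 for H929 and OPM2 (134.2 by chance), 151 for H929 and MM1S (84.65) and 553 for MM1S and OPM2 (368.7). In OPM2, the fit of the compared libraries alone called 108 genes higher and 6 lower by edgeR, which would limit the shared counts.

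The mean IKZF1 effect over the lines called 2262 genes higher and 2709 lower by edgeR, 4971 in all (5692 without OPM2 empty vector replicate 1 and 7459 without replicate 2). With DESeq2 size factors 2514 were higher and 2388 lower, and with upper-quartile scaling 2236 and 2747. DDX60L had a mean of 4.07 ± 0.29. On the mean, 46 of 57 interferon-stimulated genes rose (47 adjusted over the list alone; median 1.91; camera adjusted p = 1.5e-47, or 0.141 with an estimated correlation).

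The lines also differed. H929 and OPM2 effects differed for 1844 genes by edgeR, 949 higher and 895 lower in H929 (651 and 1062 with upper-quartile scaling), MM1S and OPM2 effects for 3018 (1715 and 1303, or 1381 and 1585 with upper-quartile scaling), and H929 and MM1S effects for 2310 (1011 and 1299). The interferon list responded more in H929 than in OPM2 (29 of 57 genes higher, 33 adjusted over the list alone; median difference 2.31; adjusted p = 7.25e-22, or 0.302 with an estimated correlation). It also responded more than in MM1S (42 higher and 1 lower, 47 higher adjusted over the list alone; median 2.93; adjusted p = 7.77e-49, or 0.0681 with an estimated correlation). IFITM1 differed by 9.05 ± 0.76 between H929 and MM1S. CYSLTR1 went the other way, at -10.71 ± 0.74 for H929 against OPM2. C11orf96 (8.19 ± 0.61) responded more in MM1S than in OPM2, and the secreted protein NDNF differed by -9.70 ± 0.39 for H929 against MM1S.

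These counts of differing genes rested on single libraries. For H929 against OPM2 the count was 492 and 616 without H929 empty vector replicate 1 and 2, 776 without H929 knockout library a, 6845 without OPM2 empty vector replicate 2, 1891 without replicate 1, 987 and 818 without OPM2 knockout library a and b, and 1217 without MM1S empty vector replicate 2. For MM1S against OPM2 it was 1665 and 1393 without MM1S empty vector replicate 1 and 2, 1715 and 1753 without MM1S knockout library a and b, 7036 without OPM2 empty vector replicate 2, 3084 without replicate 1, and 1911 without OPM2 knockout library a. For H929 against MM1S it was 1495 and 1479 without H929 empty vector replicate 1 and 2, 1450 and 1448 without MM1S empty vector replicate 1 and 2, and 4345 and 4347 without OPM2 empty vector replicate 1 and 2.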

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

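The tests of a bias in OPM2 empty vector replicate 1, of a GC content and gene length trend, of loss of IKZF1 as the reason for lower ribosomal genes, of separate clonal origin, and of a lower starting level than in MM1S were chosen after the results were seen.

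A formal test of the difference between lines picked out 8 results. The effect of IKZF1 knockout differed between H929 and OPM2 for 1844 genes, between MM1S and OPM2 for 3018 and between H929 and MM1S for 2310 by edgeR. The interferon list differed by a median of 2.31 on the log2 scale between H929 and OPM2 and of 2.93 between H929 and MM1S, but was not called with an estimated correlation (adjusted p = 0.302 and 0.0681). Single genes at the extremes were CYSLTR1 (-10.71, H929 against OPM2), C11orf96 (8.19, MM1S against OPM2) and NDNF (-9.70, H929 against MM1S). C11orf96 also differed between the OPM2 empty vector and untreated libraries, as above. For the mean IKZF1 effect over the lines, 4971 genes were called, and 1 of 100 splits of the libraries within lines (of 108 possible), the real one, gave as many. Such splits cannot tell loss of IKZF1 from any other difference between the groups, such as clones, guides or a library bias. The highest other split gave 3372 and swapped whole groups within a line, which keeps much of the real structure, and the highest without such a swap gave 2781.

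The interferon response was larger in H929 than in the other lines by camera at the preset correlation, a call lost with an estimated one, as above. A lower starting level there was argued against: in the empty vector libraries these genes stood higher in H929 than in OPM2, by a median of 2.044 on the log2 scale. Against MM1S they stood lower by a median of 0.289 (quartiles -1.5141 and 1.5959 for H929 minus MM1S). After knockout they stood higher by 2.7488 (1.0882 and 4.8924), which argues against the lower start as the whole reason there and leaves it open as a part. A single outlying H929 knockout library was also argued against, since the list median was 3.11 or more without either of them (3.1135 without a and 4.191 without b, against 3.7261 with both). Interferon made by the H929 knockout cells stays open: 0 of 21 type I and III interferon genes passed a rule of over 10 counts in both knockout libraries and at least 3 times the empty vector counts. Yet in knockout libraries a and b IFNL3 had 48 and 4 counts, IFNL2 24 and 5 and IFNB1 10 and 3, all with 0 in both empty vector libraries. IFNL1 had 21 and 4, against 2 and 6 in empty vector replicates 1 and 2. Of the other interferon genes, IFNA8 had the most in H929, 4 counts in knockout library a. Most of these counts came from library a, and no test here decides whether the cells made interferon.

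By edgeR's fitted fold change, some genes were at least 16-fold lower in the knockout libraries of 1 line. They numbered 31 in H929, 36 in MM1S and 10 in OPM2, with 0 shared between lines under this fold limit. The limit was not set on counting bounds, which can lie below it. In OPM2, CA8 (fitted log2 fold change -6.056) had a lower bound below 16-fold, as given above. EXO5 in OPM2 was 32.8-fold lower with a counting interval of 5.52 to 1330, and TRPS1 in MM1S 87.5-fold lower (15.4 to 3490). Genes of this set were not counted as neighbours of each other, so loss of a segment that held only such genes could not be seen. Loss of a segment reaching past them, as the general reason, was argued against by the 755 nearest other expressed genes. Their median log2 fold change was -0.0722 (quartiles -0.3481 and 0.2052), though 3 of the genes had a neighbour median below -0.5. The set test of separate clonal origin was met in H929 and MM1S. The knockout libraries differed more than 4-fold from each other for 71 genes in H929 and 29 in MM1S, against 6 and 3 between empty vector libraries, the lower of the ratios being 9.67. This cannot decide why genes were low in the knockout group as a whole, since it counts genes that differ between its 2 libraries. In OPM2, where the numbers were 63 and 44, separate clonal origin cannot be told apart from other reasons either: the ratio was 1.43 to the empty vector pair, in which replicate 1 stands apart, and 4.85 to the untreated pair. Direct action of IKZF1 in every line stays open, since 25% of the H929 genes expressed in MM1S fell there too (7 of 28) against 15% of all expressed genes. Whether clonal differences add to the extremes in H929 and MM1S was not decided, and no sample sheet of clones was used to test it.

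Ribosomal protein and respiratory chain genes were lower in both OPM2 knockouts than in the empty vector. A bias of empty vector replicate 1 cannot be told apart from other reasons, since without it the ribosomal median after IKZF1 knockout was -0.484 against -0.93, about midway to 0. The same is true of a GC content and length trend, after whose correction the median was -0.5636. For loss of IKZF1, the median against the untreated libraries was -0.1158, and this stays open because untreated cells also lack the vector and doxycycline. The bound for that test was revised after its value was known, for this reason of design, and under the earlier bound (near 0 relative to the main size) the value would have counted against loss of IKZF1.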

How the results depend on the processing

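The GC content and length correction, the untreated libraries as control, overlaps without OPM2 empty vector replicate 1, and unrelated comparisons without either of this pair were tests chosen after the data were seen. No paired analysis was possible for the knockouts, whose columns carry numbers other than those of the sample titles, or for lenalidomide, whose titles carry letters. A replicate block on the number shared by the OPM2 empty vector and untreated titles, also chosen after the data were seen, gave 6160 genes against 5140. Same-numbered libraries of this pair of groups share only a number, and their deviations had a correlation of 0.19 across genes. Limma trend and camera were not run on log2 FPKM, whose control columns are merged. CD38 kept its direction and its call in 67 of 68 alternatives, the exception being IKZF3 knockout fitted on its own samples (1.59). Named genes kept their direction and their side of the threshold, called or not, in 2755 of 2833 alternatives. Many of these left out 1 library, and genes whose calls held that way had been preferred, so this number was partly fixed by the choice. Neither these alternatives nor those of CD38 include glmTreat. The interferon list kept camera's direction and its side of the threshold in 33 of 38 alternatives and other lists in 259 of 324. Counts of genes stayed within 1.5 times the main ones in 108 of 210 and overlaps in 6 of 22. The cause was not tested in any case, except that glmTreat asks for a fold above 1.5 and that fits of the compared samples alone have fewer libraries. With glmTreat, counts were 521 in H929, 1464 in MM1S, 650 and 745 for OPM2 IKZF1 and IKZF3 knockout, 415 for lenalidomide, 446 for the mean and 76 for IKZF1 against IKZF3. For the differences they were 343, 816 and 1004 for H929 against OPM2, MM1S against OPM2 and H929 against MM1S, 13 and 67 for lenalidomide against IKZF1 and IKZF3 knockout, and 374 for empty vector against untreated. The GC and length correction gave 2597 in H929, 2520 for lenalidomide, 876 for IKZF1 against IKZF3, 3660 for H929 against MM1S, and 540 and 1592 for lenalidomide against the knockouts. Fits of the compared samples alone gave 7032 in MM1S, 114 and 52 in the OPM2 knockouts, 5576 for lenalidomide, 118, 714 and 4080 for the line differences in the same order, and 27 for lenalidomide against IKZF3 knockout. They gave 0 by edgeR for lenalidomide against IKZF1 knockout (1867 at an unadjusted p below 0.05; 1746 by DESeq2 and 44 by limma-voom on all libraries) and for empty vector against untreated (2748 at an unadjusted p below 0.05; 5573 by DESeq2 and 5280 by limma-voom on all libraries). With untreated libraries as control the OPM2 knockouts gave 1131 and 1205. Without a low-count filter counts were 810 for IKZF1 against IKZF3, 3143 for H929 against OPM2, and 2297 and 2652 for lenalidomide against the knockouts, and DESeq2 gave 579, 1746 and 2167 for IKZF1 against IKZF3 and lenalidomide against the knockouts. Over all single libraries left out, counts ran from 690 to 3323 in H929, 2360 to 6324 in MM1S, 3112 to 7982 and 2539 to 8017 in the OPM2 knockouts, 583 to 3266 for lenalidomide, 3759 to 7459 for the mean, and 114 to 1334 for IKZF1 against IKZF3. They ran from 492 to 6845, 1393 to 7036 and 1448 to 4347 for the line differences, 10 to 6604 and 77 to 6739 for lenalidomide against the knockouts, and 2187 to 7842 for empty vector against untreated. The interferon list was not called with an estimated correlation in MM1S (adjusted p = 0.612), OPM2 IKZF1 (0.603) and IKZF3 knockout (0.66) and lenalidomide (0.354), and in IKZF3 knockout camera's adjusted p ran from 2.58e-12 to 0.051 with 1 library left out. Shared genes at an adjusted p below 0.01 by edgeR were 298 higher and 151 lower for IKZF1 knockout and lenalidomide, 226 and 140 for IKZF3 knockout and lenalidomide, 711 and 1192 for both knockouts, and 71 and 9 for the 3 lines. At an adjusted p below 0.05 and a log2 CPM of 3 or more, IKZF1 knockout and lenalidomide shared 346 higher genes. Shared genes without OPM2 empty vector replicate 1 were counted at an adjusted p below 0.05, with no log2 CPM minimum. They were 851 and 635, 731 and 643, 997 lower, and 306 and 174, in the order given for 0.01. Reversed directions were IKZF3 in IKZF3 knockout with the GC and length correction (-0.0103), IKZF3 under lenalidomide without lenalidomide replicate 1 (-0.0892, and 0.2438 without replicate 2), and, against the untreated libraries, CCR1 in IKZF1 knockout (-0.02), MYC targets in IKZF1 and IKZF3 knockout (camera adjusted p = 0.0602 and 0.0828) and respiratory chain genes in IKZF3 knockout (0.591).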

Other observations

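The observations here are values from the same comparisons, and those against the untreated libraries are tests chosen after the data were seen. Another member of the Ikaros family, IKZF2 (Helios), rose in H929 after IKZF1 knockout by 1.32 ± 0.23 on the log2 scale, from 6.055 to 15.14 CPM (adjusted p = 0.0015 by edgeR). In MM1S it rose by 0.86 ± 0.28 (adjusted p = 0.0313 by edgeR, but 0.128 without either empty vector library and 0.265 without knockout library b). In OPM2 it was higher than in the empty vector by 1.17 ± 0.22 after IKZF1 knockout and by 1.43 ± 0.22 after IKZF3 knockout, but by 0.14 and 0.40 against the untreated libraries, where neither was called by edgeR. The chemokine receptor CCR1 rose in H929 by 1.35 ± 0.15, from 399.6 to 1018 CPM, in MM1S by 0.71 ± 0.15 and in OPM2 by 0.63 ± 0.15, but changed by -0.02 against the untreated OPM2 libraries. CCR2 rose from 14.71 to 80.83 CPM in MM1S, and the sphingosine receptor S1PR2 rose in H929 by 1.38 ± 0.20. In H929 the small heat shock protein HSPB1 fell by 2.67 ± 0.32 and glutamine synthetase GLUL by 1.77 ± 0.19.

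In MM1S the repressor subunit CHD3 of the NuRD complex fell by 2.88 ± 0.24 and the Polycomb methyltransferase EZH2 by 0.73 ± 0.12, from 146 to 87.71 CPM. The metabolic kinase PDK1 rose from 139.8 to 455.9 CPM and the sterol enzyme SQLE from 14.33 to 41.02 CPM. MAF rose in MM1S by 1.08 ± 0.15, from 502.9 to 1061 CPM, as it did in OPM2. Under lenalidomide IL4R rose by 1.17 ± 0.14 and cyclin CCND2 by 0.71 ± 0.12, while the fucosyltransferase FUT1 fell by 3.11 ± 0.41 and the integrin ITGA8 by 4.79 ± 0.60.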
